A study of Mus musculus with 116 samples.

How the data were processed

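RNA of mouse FDB1 cells was measured on spotted 2-colour arrays, with Cy5 in channel 1 and Cy3 in channel 2 per the labels. The labels give 18 conditions with 2 replicates each, so 36 RNAs: parental cells at 0 hours, parental cells at 5 times (6, 12, 24, 48 and 72 hours) in GM-CSF, and V449E and FI-Delta cells at 0 hours and at the same 5 times. The arrays form 58 dye-swap pairs over 28 comparisons, and every array holds RNAs of 1 replicate number. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, array noise included. Array noise made up a median of 75.7% of the variance of the fitted RNA levels.

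The deposited values were read as log2 ratios. The sample descriptions state that the authors normalised the arrays and then put the spots of both print runs in 1 order, and the processing notes name limma without a version. Neither the log base nor the direction is stated in the deposited files: log2 of Cy5 over Cy3 is likely, because limma writes that ratio and the labels give Cy5 as channel 1. Background correction and the normalisation method are not stated in the labels or the files. Array medians ran from -0.016 to 0.011, the median absolute deviation from 0.0865 to 0.198, and single values from -7.05 to 5.28. Signal intensities were not used here, so the signal over background behind a value is unknown, and the number of arrays limits the precision. In all 58 dye-swap pairs the arrays correlated negatively across probes (r from -0.653 to -0.0327). Turning all signs would leave these correlations unchanged, so they do not bear on the direction. The check of direction was fixed beforehand. After 72 hours in GM-CSF the macrophage and late granule lists should rise and the cell cycle lists fall. The sign of these lists there is therefore not independent evidence. The first 2 lists and G1/S went that way, and G2/M went the other way without passing (median log2 0.09, adjusted p = 0.0615), so this check was met in part.

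Print run 1 holds 90 arrays and print run 2 holds 26. Print run 2 holds every replicate 2 array of the GM-CSF time course, of FI-Delta against GM-CSF and of FI-Delta against parental cells at 0 hours. It also holds a repeat of V449E against parental cells at 0 hours for both replicates. Of 23040 probes, 1243 controls were left out and 21797 were tested, none with a missing value. Symbols were updated through the Entrez identifiers: 16651 tested probes had 1 symbol, 137 had several and 5009 had none, giving 15097 symbols. No genome coordinates were used.

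Each dye-swap pair was averaged, and least squares within each replicate gave each of the 18 RNAs a level relative to the mean of its replicate. Differences between conditions were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 36 levels, with replicate number as a block. All levels were weighted equally, although a condition lay on 8 to 32 arrays. The levels are centred within replicates, so the block only counts the degree of freedom that centring uses, which left 17 residual and 5.99 prior degrees of freedom. Benjamini-Hochberg adjustment was made over probes within a comparison, with a threshold of 0.05, and tests were 2-sided. The median standard error of a difference was 0.09 on the log2 scale. Differences between 72-hour responses of 2 lines were tested in the same model. The fit was tested on 1 simulated data set per line with 200 changed probes of 21797, drawn at random. In the GM-CSF comparison at 72 hours it found 70.1% of changes of 0.5 and 100% of changes of 1 on the log2 scale, with no false call among 180. In the V449E comparison it found 83.6% and 100%, with 1.05% false calls, and in the FI-Delta comparison 86.6% and 100%, with 2.05% false calls. These shares vary from draw to draw.

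The comparisons, their tests and the alternatives named below were fixed before the data were examined, and what was chosen later is named as such where it is given. Fixed with them were 22 gene lists: G1/S and DNA replication, G2/M and mitosis, cell cycle exit, primary granule, late granule, macrophage, mast cell and basophil, progenitor regulators, STAT5 targets, ERK targets, BCL2 family and death, p53 targets, ribosome biogenesis, glycolysis, cholesterol synthesis, interferon response, MHC class II and costimulation, NADPH oxidase, inflammatory cytokines, ATF4 and ER stress, erythroid and megakaryocyte, and lymphoid. Probes of 1 symbol were averaged for these lists, so a list member can differ slightly from the single probe named for the same gene. Each list was tested with camera in limma at a preset correlation of 0.01 between genes and, beside it, at an estimated correlation, adjusted over 132 tests (22 lists by 6 comparisons). Of these tests 59 passed at the preset and 2 with an estimated correlation. For the other times, 484 tests were adjusted together, of which 212 and 19 passed.

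Named genes were chosen by a rule: for each of the 6 main comparisons, among probes past the threshold with the same sign in both replicates and 1 symbol, the 8 with the largest rise and the 8 with the largest fall, then list members by size, and the receptor genes Csf2rb, Csf2rb2, Csf2ra and Il3ra. No probe carried Csf2rb alone. A gene named outside the rule is said to have been chosen after its values were seen. Correlations of responses were set beside the mean of 20 simulations of unchanged data on the same arrays, because the fitted levels of the lines are linked through the arrays between lines. Alternatives tried were limma on single arrays, with and without a dye effect per print run, limma on dye-swap means, direct arrays only, no replicate block, median-centred arrays, scaled arrays, no print run 2 arrays, complete probes only and at least 1 orientation per pair (both the same fit here, since no value was missing), robust moderation, probes averaged per symbol, and leaving out each RNA of a comparison in turn.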

Results

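The data are log2 ratios from 58 dye-swap pairs of 2-colour arrays. They follow FDB1 cells, a mouse myeloid line that depends on added growth factor, in a factorial time course. Parental cells grew in 500 U/mL of IL-3 with 10% serum and were moved to 500 U/mL of GM-CSF. Cells carrying the V449E or the FI-Delta receptor mutant grew in the same IL-3 medium and were then left without factor. Samples were taken at 0 hours, when IL-3 was washed out, and at 6, 12, 24, 48 and 72 hours. Each value below rests on n = 2 RNAs for each of the 18 conditions unless stated. Each comparison of 2 conditions was made on 4 arrays, and V449E against parental cells at 0 hours on 8. Differences are on the log2 scale with the standard error (SE) of the fit, and the direction of the deposited ratios is taken as Cy5 over Cy3, which is likely but not stated.

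The first comparison asks what the switch from IL-3 to GM-CSF changes in parental cells. After 72 hours in GM-CSF the macrophage list was higher at both correlations of the test, and the late granule list at the preset one only. Stfa3, a stefin that inhibits cysteine proteases, rose by 2.39 (SE 0.40, adjusted p = 6.17e-04), a 5.25-fold change. Clec4n, the C-type lectin dectin-2, rose by 2.34 (SE 0.26, adjusted p = 6.46e-06) and Mmp8, the neutrophil collagenase, by 2.20 (SE 0.21, adjusted p = 1.06e-06). Bcl2a1d, an anti-apoptotic BCL2 relative, rose by 2.08 (SE 0.15) and Bcl2a1c by 1.77 (SE 0.20). Psap, the precursor of lysosomal saposins, rose by 1.89 (SE 0.28), Upp1, a uridine phosphorylase, by 1.70 (SE 0.19) and Stfa1 by 1.69 (SE 0.41). The largest falls were of Tmtc2 at -2.52 (SE 0.31, adjusted p = 2.32e-05) and Rab27b, a GTPase of secretory granules, at -2.05 (SE 0.25). F2r, the thrombin receptor, was lower at -2.04 (SE 0.23) and Tnfsf11, the cytokine RANKL, at -1.73 (SE 0.44). Sytl3, a Rab27 effector, fell by 1.70 on the log2 scale and Ikzf2, a zinc finger transcription factor, by 1.53. Cpa3, the mast cell carboxypeptidase, fell by 1.70 on the log2 scale and Gata2, a progenitor and mast cell transcription factor, by 1.23. Csf2ra, the ligand-binding chain of the GM-CSF receptor, rose by 0.89 (SE 0.15, adjusted p = 8.62e-04). Csf2rb2, the beta chain used by IL-3, was -0.39 (SE 0.22) and Il3ra 0.07 (SE 0.06), and neither passed. Over all probes, 637 rose and 555 fell, 58 and 21 of them at least 2-fold. The replicate responses correlated across probes at r = 0.49. The count of 1192 became 411 without parental 0 hours replicate 1 and 567 without replicate 2. It became 749 without GM-CSF 72 hours replicate 1 and 722 without GM-CSF 72 hours replicate 2. Without parental replicate 1 or GM-CSF replicate 2, Stfa1 (1.37 and 1.28) and Tnfsf11 (-1.51 and -1.38) no longer passed. The same held for Gata2 (-1.08) without parental replicate 2.

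Among the gene lists, 24 of 45 measured macrophage genes rose in GM-CSF (30 adjusted over the list alone). Among these were Ccr2, a chemokine receptor, at 1.62 (SE 0.19) and Ctss, a lysosomal cathepsin, at 1.54 (SE 0.21). Mpeg1, the pore protein perforin-2, rose by 1.31 (SE 0.23) and Itgam, an adhesion integrin, by 1.14 (SE 0.19). The macrophage list had a median log2 of 0.45 (adjusted p = 2.64e-20, and adjusted p = 0.0136 with an estimated correlation). Of 22 late granule genes 7 rose (8 adjusted over the list alone). Beside Mmp8 these held Lcn2, an iron-binding granule lipocalin, at 1.38 (SE 0.37) and Fpr2, a formyl peptide receptor, with a 2.14-fold rise (adjusted p = 0.0165). The late granule list had a median log2 of 0.39 (adjusted p = 2.54e-07, and adjusted p = 0.0942 with an estimated correlation). Of 31 ribosome biogenesis genes 19 fell (23 fell and 1 rose adjusted over the list alone). The nucleolar proteins Nop56 and Npm1 were at -0.80 (SE 0.15) and -0.66 (SE 0.09). The ribosome biogenesis list had a median log2 of -0.41 (adjusted p = 2.64e-20, and adjusted p = 0.0547 with an estimated correlation). In the ATF4 and ER stress list 6 of 22 fell (9 adjusted over the list alone). Atf4, a stress transcription factor, was lower at -0.83 (SE 0.23) and Shmt2, a mitochondrial serine enzyme, at -0.77 (SE 0.12), while Cebpb, a myeloid transcription factor, rose by 1.03 (SE 0.13). The ATF4 list had a median log2 of -0.32 (adjusted p = 1.46e-06, and adjusted p = 0.0942 with an estimated correlation). Of 21 mast cell and basophil genes 4 fell (4 adjusted over the list alone). They were Cpa3, Gata2, Mcpt8, a basophil protease, at -1.07 (SE 0.20) and Fcer1a, the IgE-binding receptor chain, at -1.03 (SE 0.14). The mast cell list had a median log2 of -0.09 (adjusted p = 0.00153, and adjusted p = 0.0942 with an estimated correlation). Of 5 NADPH oxidase genes 3 rose (4 adjusted over the list alone), led by Cybb, the catalytic subunit, at 0.90 (SE 0.26). The NADPH oxidase list had a median log2 of 0.41 (adjusted p = 0.00175, and adjusted p = 0.107 with an estimated correlation). Of 20 cell cycle exit genes 4 rose (5 adjusted over the list alone), led by Mxd1, a MAX partner that opposes MYC, at 1.01 (SE 0.23). The cell cycle exit list had a median log2 of 0.21 (adjusted p = 7.78e-04, and adjusted p = 0.0942 with an estimated correlation). The signs of the macrophage, late granule and cell cycle lists here checked the direction of the ratios and are not independent evidence. Of the 4, G2/M and mitosis did not go the way set beforehand. Its median log2 was 0.09 (adjusted p = 0.0615, and adjusted p = 0.797 with an estimated correlation), with 2 higher and 0 lower of 37 genes at an unadjusted p under 0.05 in limma, and it passed as higher without GM-CSF 72 hours replicate 1 (0.19, adjusted p = 5.46e-04) or parental 0 hours replicate 2 (0.13, adjusted p = 0.00773).

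A further 6 lists passed at the preset correlation in GM-CSF at 72 hours and none of these did so with an estimated one. ERK target genes had 5 of 28 higher (6 higher and 1 lower adjusted over the list alone). Dusp6, an ERK phosphatase, was at 1.23 (SE 0.28). The ERK target list had a median log2 of 0.13 (adjusted p = 0.00472, and adjusted p = 0.375 with an estimated correlation). In the BCL2 family 5 rose and 1 fell of 24 (5 and 3 adjusted over the list alone), led by Bcl2a1d and Bcl2a1a at 1.66 (SE 0.21). The BCL2 family list had a median log2 of 0.11 (adjusted p = 0.00602, and adjusted p = 0.107 with an estimated correlation). Among inflammatory cytokine genes 4 of 22 rose (5 adjusted over the list alone). Ccl6, a myeloid chemokine, was at 1.20 (SE 0.15) and Il1b, the cytokine interleukin-1 beta, at 1.11 (SE 0.31). The list had a median log2 of 0.20 (adjusted p = 0.0211, and adjusted p = 0.317 with an estimated correlation). In the MHC class II list 3 of 13 fell and 1 rose (3 and 1 adjusted over the list alone), with the antigen-presenting chain H2-Eb1 at -0.96 (SE 0.29). The MHC class II list had a median log2 of -0.21 (adjusted p = 0.0170, and adjusted p = 0.431 with an estimated correlation). Cholesterol synthesis had 2 of 19 lower, also 2 adjusted over the list alone. The list had a median log2 of -0.11 (adjusted p = 0.0107, and adjusted p = 0.563 with an estimated correlation). In G1/S and DNA replication only Mcm3, a subunit of the replicative helicase, fell, at -0.47 (SE 0.14), 1 of 34 measured, and it did not pass adjusted over the list alone. The G1/S list had a median log2 of -0.09 (adjusted p = 0.0111, and adjusted p = 0.628 with an estimated correlation). Without parental 0 hours replicate 2, the ERK list turned to a median of -0.04 (adjusted p = 0.968). Also without that RNA, cell cycle exit (adjusted p = 0.267), BCL2 family (adjusted p = 0.310), inflammatory cytokines (adjusted p = 0.476), G1/S (adjusted p = 0.508) and cholesterol synthesis (adjusted p = 0.0662) no longer passed. G1/S (adjusted p = 0.523), cholesterol synthesis (adjusted p = 0.507) and inflammatory cytokines (adjusted p = 0.0632) were lost without GM-CSF 72 hours replicate 1. MHC class II was lost without parental replicate 1 (adjusted p = 0.108) or GM-CSF 72 hours replicate 2 (adjusted p = 0.382).

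FI-Delta cells left without factor for 72 hours had higher RNA of the late granule list, and lower RNA of the ribosome biogenesis list, than the same cells in IL-3. Both lists passed at the preset correlation and missed the threshold with an estimated one (adjusted p = 3.81e-11 and adjusted p = 8.25e-19, against adjusted p = 0.0547 for each). Ltf, the granule protein lactoferrin, rose by 2.68 (SE 0.60, adjusted p = 0.00338) and Camp, the antimicrobial peptide cathelicidin, by 1.79 (SE 0.46, adjusted p = 0.00966). Fos, a subunit of the AP-1 transcription factor, rose by 1.97 (SE 0.23, adjusted p = 7.08e-06), Fosb by 1.77 (SE 0.37) and Egr1, an immediate early transcription factor, by 1.74 (SE 0.34). Psap rose by 1.87 (SE 0.28) and 1700054A03Rik by 2.61 (SE 0.44). Neb, which encodes nebulin, rose by 1.88 (SE 0.27) on 1 of its 4 probes. Tmtc2 was lower at -3.10 (SE 0.31, adjusted p = 7.65e-07), an 8.57-fold change, and Cpa3 at -2.87 (SE 0.24, adjusted p = 9.42e-08). F2r was lower at -2.63 (SE 0.23), Rab27b at -2.28 (SE 0.25) and Ikzf2 at -2.14 (SE 0.14). H2-Eb1 fell by 1.58 on the log2 scale, Tnfsf11 by 1.77 and Sytl3 by 1.67. Csf2ra rose by 0.89 (SE 0.15, adjusted p = 3.64e-04). Csf2rb2 was -0.48 (SE 0.22) and Il3ra 0.02 (SE 0.06), and neither passed. In all, 1472 probes rose and 1854 fell, 93 and 55 of them at least 2-fold. Replicate responses correlated at r = 0.81 across probes. The count of 3326 became 1053 without FI-Delta 0 hours replicate 1, 1322 without FI-Delta 72 hours replicate 1 and 1455 without FI-Delta 0 hours replicate 2. Without FI-Delta 0 hours replicate 1, Ltf (1.98), Camp (1.26), Egr1 (1.36), Fosb (1.25), Tnfsf11 (-1.70) and H2-Eb1 (-1.11) no longer passed. The same held for Fosb (0.98) and Tnfsf11 (-1.84) without FI-Delta 72 hours replicate 1, and for Camp (adjusted p = 0.103) without FI-Delta 72 hours replicate 2.

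Of 31 ribosome biogenesis genes in FI-Delta cells at 72 hours 25 fell and 1 rose, also 25 and 1 adjusted over the list alone. Nop56 was at -1.37 (SE 0.15) and Bop1, a nucleolar protein, at 0.28 (SE 0.08). The list had a median log2 of -0.56 (adjusted p = 8.25e-19, and adjusted p = 0.0547 with an estimated correlation). Late granule genes rose for 13 of 22 (17 adjusted over the list alone). Ngp, a neutrophil granule protein, was at 1.58 (SE 0.53), Padi4, an enzyme of histone citrullination, at 1.31 (SE 0.19) and Mmp8 at 1.47 (SE 0.22). The late granule list had a median log2 of 0.73 (adjusted p = 3.81e-11, and adjusted p = 0.0547 with an estimated correlation). Macrophage genes rose for 20 of 45 (26 adjusted over the list alone). Ctss was at 1.30 (SE 0.21) and Itgam at 1.07 (SE 0.19). The macrophage list had a median log2 of 0.43 (adjusted p = 1.63e-10, and adjusted p = 0.0706 with an estimated correlation). ERK targets rose for 15 of 28 and fell for 1 (17 and 1 adjusted over the list alone). Egr3, an immediate early gene, was at 1.58 (SE 0.39), Zfp36, an mRNA decay factor, at 1.17 (SE 0.20) and Spry4, an inhibitor of receptor signalling, at -0.31 (SE 0.08). The ERK target list had a median log2 of 0.45 (adjusted p = 3.23e-07, and adjusted p = 0.107 with an estimated correlation). G1/S genes fell for 13 of 34 (17 adjusted over the list alone). The replicative helicase subunits Mcm6 and Mcm3 were at -0.81 (SE 0.15) and -0.76 (SE 0.14). The G1/S list had a median log2 of -0.25 (adjusted p = 6.47e-06, and adjusted p = 0.317 with an estimated correlation). In the ATF4 list 6 of 22 fell, also 6 adjusted over the list alone. The serine synthesis enzymes Psat1 and Phgdh were at -1.10 (SE 0.14) and -1.09 (SE 0.11). The ATF4 list had a median log2 of -0.24 (adjusted p = 4.09e-04, and adjusted p = 0.168 with an estimated correlation). MHC class II genes fell for 8 of 13 (8 fell and 1 rose adjusted over the list alone). H2-Ea was at -1.33 (SE 0.32) and H2-Aa at -1.19 (SE 0.18). The list had a median log2 of -0.57 (adjusted p = 7.78e-04, and adjusted p = 0.242 with an estimated correlation). NADPH oxidase genes rose for 4 of 5, also 4 adjusted over the list alone, with Cybb at 1.28 (SE 0.26). The list had a median log2 of 0.46 (adjusted p = 0.00153, and adjusted p = 0.107 with an estimated correlation). Cell cycle exit genes rose for 5 of 20 (7 adjusted over the list alone), with Mxd1 at 1.21 (SE 0.23) and Btg2, an antiproliferative factor, at 1.00 (SE 0.12). The list had a median log2 of 0.18 (adjusted p = 0.00153, and adjusted p = 0.106 with an estimated correlation). Cholesterol synthesis genes fell for 5 of 19, also 5 adjusted over the list alone. The list had a median log2 of -0.19 (adjusted p = 0.00438, and adjusted p = 0.515 with an estimated correlation). It did not pass without FI-Delta 72 hours replicate 1 (adjusted p = 0.0531). The progenitor list did not pass as a group (median log2 -0.12, adjusted p = 0.197), but 8 of its 26 genes fell and 3 rose (8 and 6 adjusted over the list alone). Cd34, a progenitor surface protein, was at -1.21 (SE 0.19), Sox4, a transcription factor, at -0.98 (SE 0.11) and Id2, an inhibitor of helix-loop-helix factors, at 1.01 (SE 0.21). The mast cell list did not pass either (median log2 -0.05, adjusted p = 0.263), with 5 of 21 lower and 1 higher, also 5 and 1 adjusted over the list alone. Fcer1a was at -1.24 (SE 0.14) and Gata2 at -1.15 (SE 0.19).

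V449E cells left without factor changed at 6, 12 and 24 hours, and by 72 hours no probe passed against the same cells in IL-3 in limma. At 12 hours STAT5 target genes were lower: 8 of 19 fell (11 adjusted over the list alone). Id1, an inhibitor of helix-loop-helix factors, was at -1.11 (SE 0.20). The feedback inhibitors of cytokine signalling Socs1 and Cish were at -0.997 (SE 0.16) and -0.94 (SE 0.19), the survival gene Bcl2l1 at -0.60 (SE 0.15) and the kinase gene Pim1 at -0.57 (SE 0.14). The STAT5 list had a median log2 of -0.40 (adjusted p = 2.84e-13, and adjusted p = 0.0231 with an estimated correlation). At 24 hours 8 of 45 macrophage genes were higher (17 adjusted over the list alone). The macrophage list had a median log2 of 0.15 (adjusted p = 4.63e-07, and adjusted p = 0.135 with an estimated correlation). The following were chosen after their values were seen. At 6 hours Clec4e, a C-type lectin, was at 1.63 (SE 0.24) and Slc7a11, the cystine transporter, at 1.38 (SE 0.18). Myc, a growth regulator, was at -0.83 (SE 0.16) and Tmtc2 at -1.80 (SE 0.31). At 24 hours Fth1, the heavy chain of ferritin, was at 1.60 (SE 0.24), Lipa, lysosomal acid lipase, at 1.43 (SE 0.17) and Atf4 at -1.08 (SE 0.23). The counts of probes higher and lower than at 0 hours were 85 and 68 at 6 hours, 117 and 161 at 12 hours, and 153 and 162 at 24 hours. At 48 hours 1 probe was higher, Ms4a7, at 1.00 (SE 0.14, adjusted p = 0.00926), chosen after its values were seen. At 72 hours limma called 0 probes, with 933 at an unadjusted p under 0.05 where 1090 would be drawn by chance, and the smallest adjusted p was 0.408. Limma on single arrays called 266, with a dye effect 370, on dye-swap means 31 and on direct arrays 29. The replicate responses correlated at r = 0.21 across probes. Leaving out V449E 72 hours replicate 2 gave 47 called probes and leaving out replicate 1 gave 9. Of the 3326 probes changed in FI-Delta cells, 1376 had a 95% interval in V449E cells that excluded 0.5 times the FI-Delta change. Csf2ra was -0.07 (SE 0.15), Csf2rb2 -0.09 (SE 0.22) and Il3ra 0.0036 (SE 0.06) at 72 hours, and none of the 3 passed.

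No list member passed in V449E cells at 72 hours over all genes, and adjusted over the list alone 1 macrophage gene and 1 ATF4 gene did. At the preset correlation the ribosome biogenesis list was lower, with a median log2 of -0.08 (adjusted p = 3.44e-05, and adjusted p = 0.293 with an estimated correlation) and 3 of 31 genes lower at an unadjusted p under 0.05 in limma. Cholesterol synthesis was lower, with a median of -0.14 (adjusted p = 1.99e-04, and adjusted p = 0.365 with an estimated correlation) and 1 of 19 genes at that limit. The macrophage list was higher, with a median of 0.05 (adjusted p = 0.00271, and adjusted p = 0.317 with an estimated correlation), and 5 of 45 genes were higher and 1 lower at that limit. G2/M and mitosis was higher, with a median of 0.10 (adjusted p = 0.00449, and adjusted p = 0.668 with an estimated correlation) and 2 of 37 genes at that limit. Inflammatory cytokines were lower, with a median of -0.11 (adjusted p = 0.0378, and adjusted p = 0.375 with an estimated correlation) and no gene of 22 at that limit. The lymphoid list was lower, with a median of -0.02 (adjusted p = 0.0455, and adjusted p = 0.107 with an estimated correlation) and 2 of 19 genes at that limit. Other lists passed only when 1 RNA was left out. List medians ran from -0.27 to 0.08 without V449E 0 hours replicate 1 and from -0.15 to 0.22 without V449E 0 hours replicate 2. Each of the 6 list results above was lost when 1 RNA was left out. Those lost without V449E 72 hours replicate 2 were ribosome biogenesis (adjusted p = 0.107), macrophage (adjusted p = 0.0959), G2/M (adjusted p = 0.109), inflammatory cytokines (adjusted p = 0.117) and lymphoid (adjusted p = 0.0664). Cholesterol synthesis was lost without V449E 0 hours replicate 2 (adjusted p = 0.430) or V449E 72 hours replicate 1 (adjusted p = 0.0854). Without V449E 0 hours replicate 1, macrophage (adjusted p = 0.0516), G2/M (adjusted p = 0.202), inflammatory cytokines (adjusted p = 0.676) and lymphoid (adjusted p = 0.202) also missed the threshold. The same held for inflammatory cytokines (adjusted p = 0.180) and lymphoid (adjusted p = 0.180) without V449E 72 hours replicate 1.

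**Figure D1:**
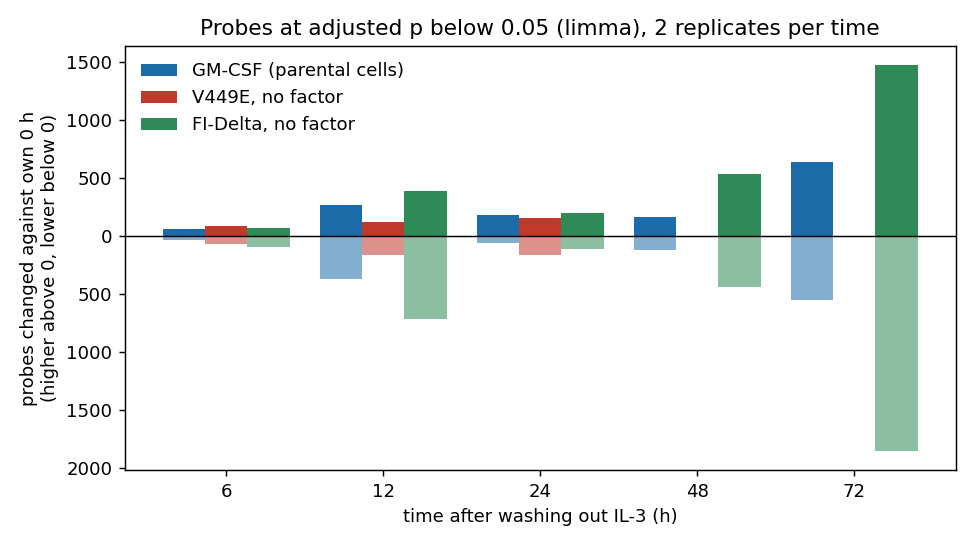
Number of probes past an adjusted p of 0.05 in limma (vertical axis, higher above 0 and lower below 0) against hours after IL-3 was washed out, for parental cells in GM-CSF and for V449E and FI-Delta cells without factor, each against its own 0 hours with 2 replicates. In V449E cells the bars reach 153 and 162 at 24 hours and 0 at 72 hours, where 933 probes had an unadjusted p under 0.05 and limma on single arrays called 266, while FI-Delta cells reach 1472 and 1854 at 72 hours.

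At 72 hours V449E cells had lower RNA of the late granule list than FI-Delta cells at both correlations of the test. MHC class II RNA was higher at the preset correlation only. Tmtc2 was higher in V449E cells by 3.69 (SE 0.31, adjusted p = 1.99e-08) and Cpa3 by 3.02 (SE 0.24, adjusted p = 9.75e-09). Rab27b was higher by 2.83 (SE 0.25), F2r by 2.69 (SE 0.23) and Tnfsf11 by 2.60 (SE 0.44). H2-Eb1 was higher by 2.46 (SE 0.29), Ikzf2 by 2.42 (SE 0.14) and S100a10, a partner of annexin A2, by 2.22 (SE 0.17). Stfa3 was lower at -4.59 (SE 0.40, adjusted p = 3.58e-08), a 24.0-fold difference, and Ltf at -4.06 (SE 0.60, adjusted p = 4.21e-05). Also lower were Stfa1 at -3.62 (SE 0.41), Wfdc21 at -3.34 (SE 0.26) and 1700054A03Rik at -3.45 (SE 0.44). Late granule genes were lower for 18 of 22 (21 adjusted over the list alone). Lcn2 was at -3.29 (SE 0.37), Camp at -3.23 (SE 0.47) and Ngp at -3.11 (SE 0.53). The late granule list had a median log2 of -1.33 (adjusted p = 3.45e-18, and adjusted p = 0.0136 with an estimated correlation). MHC class II genes were higher for 9 of 13 and lower for 1 (9 and 2 adjusted over the list alone). H2-Aa was higher by 1.64 (SE 0.18). The MHC class II list had a median log2 of 0.82 (adjusted p = 3.13e-06, and adjusted p = 0.107 with an estimated correlation). Mast cell genes were higher for 6 of 21 and lower for 2, also 6 and 2 adjusted over the list alone. Fcer1a was at 2.14 (SE 0.14) and Ccl3, a chemokine, at -1.83 (SE 0.59). The mast cell list had a median log2 of 0.07 (adjusted p = 0.0266, and adjusted p = 0.201 with an estimated correlation). Csf2ra was lower at -1.02 (SE 0.15, adjusted p = 5.22e-05) and Csf2rb2 higher by 0.79 (SE 0.22, adjusted p = 0.0165), while Il3ra at 0.12 (SE 0.06) did not pass. In all, 1966 probes were higher and 1668 lower in V449E cells, 109 and 157 of them at least 2-fold. Replicates correlated at r = 0.78 across probes. The total of 3634 became 2076 without FI-Delta 72 hours replicate 1 and 2346 without V449E 72 hours replicate 2.

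Ribosome biogenesis genes were higher in V449E than in FI-Delta cells at 72 hours for 24 of 31 and lower for 1 (25 and 1 adjusted over the list alone). Nop56 was at 0.90 (SE 0.15) and Odc1, the first enzyme of polyamine synthesis, at 0.68 (SE 0.11). The ribosome biogenesis list had a median log2 of 0.42 (adjusted p = 1.06e-11, and adjusted p = 0.0942 with an estimated correlation). ERK targets were lower for 17 of 28 and higher for 1, also 17 and 1 adjusted over the list alone. Fos was at -1.74 (SE 0.24) and Egr1 at -1.78 (SE 0.34). The ERK target list had a median log2 of -0.57 (adjusted p = 8.67e-08, and adjusted p = 0.106 with an estimated correlation). Macrophage genes were lower for 16 of 45 and higher for 2 (19 and 2 adjusted over the list alone). Itgam was at -1.41 (SE 0.19) and Fcgr1, a high-affinity IgG receptor, at -0.999 (SE 0.14). The macrophage list had a median log2 of -0.32 (adjusted p = 6.30e-07, and adjusted p = 0.106 with an estimated correlation). NADPH oxidase genes were lower for 4 of 5, also 4 adjusted over the list alone, with Cybb at -2.01 (SE 0.26). The NADPH oxidase list had a median log2 of -0.63 (adjusted p = 3.24e-05, and adjusted p = 0.0706 with an estimated correlation). In the ATF4 list 10 of 22 were higher and 2 lower (12 and 2 adjusted over the list alone). Psat1 was at 1.01 (SE 0.14) and Cebpb at -0.80 (SE 0.13). The ATF4 list had a median log2 of 0.38 (adjusted p = 4.16e-05, and adjusted p = 0.116 with an estimated correlation). Inflammatory cytokines were lower for 10 of 22 and higher for 2 (11 and 2 adjusted over the list alone), with Il1b at -2.21 (SE 0.31). The list had a median log2 of -0.41 (adjusted p = 0.00511, and adjusted p = 0.214 with an estimated correlation). Cell cycle exit genes were lower for 5 of 20 (6 adjusted over the list alone), with Mxd1 at -2.93 (SE 0.23). The cell cycle exit list had a median log2 of -0.22 (adjusted p = 0.00766, and adjusted p = 0.142 with an estimated correlation). G1/S genes were higher for 9 of 34 and lower for 1 (10 and 1 adjusted over the list alone). The G1/S list had a median log2 of 0.14 (adjusted p = 0.0285, and adjusted p = 0.672 with an estimated correlation). The G1/S result was lost without FI-Delta 72 hours replicate 1 (adjusted p = 0.485) or V449E 72 hours replicate 1 (adjusted p = 0.0996), and the inflammatory cytokine result without FI-Delta 72 hours replicate 1 (adjusted p = 0.119). The STAT5 list did not pass (median log2 0.04, adjusted p = 0.305), with 6 of 19 higher and 2 lower (6 and 3 adjusted over the list alone). Socs1 was higher at 0.99 (SE 0.16) and Pim2, a survival kinase, at 0.97 (SE 0.19), and Ccnd2, a D-type cyclin, was lower at -0.84 (SE 0.19).

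V449E and FI-Delta cells already differed at 0 hours in IL-3, and the number of probes that differed between these 2 lines grew with time. Single genes varied. Between 0 and 72 hours the V449E difference from FI-Delta cells went from 0.40 to 3.69 for Tmtc2. For S100a10 it was 2.24 and 2.22, for S100a9 -2.51 and -2.57, and for Stfa1 -3.11 and -3.62. Against FI-Delta cells, V449E cells had 25 probes higher and 24 lower at 0 hours, 82 and 96 at 6 hours, 95 and 146 at 12 hours, 321 and 413 at 24 hours and 804 and 1000 at 48 hours. Late granule genes were lower in V449E cells at 0 hours for 3 of 22 (9 adjusted over the list alone), Lcn2 at -2.02 (SE 0.37) and the calprotectin subunits S100a8 at -2.41 (SE 0.44) and S100a9 at -2.51 (SE 0.49). The list median there was -0.36 (adjusted p = 1.25e-13, and adjusted p = 0.0262 with an estimated correlation). At 24 hours 13 were lower (18 adjusted over the list alone). Their list median was -0.86 (adjusted p = 9.62e-20, and adjusted p = 0.0206 with an estimated correlation). To ask whether the 72-hour responses themselves differed, the change from 0 hours was compared between lines. V449E and FI-Delta cells differed at 783 probes, V449E and GM-CSF cells at 137, and FI-Delta and GM-CSF cells at 1. In the first of these, Tmtc2 (3.29 (SE 0.43)), Cpa3 (2.78 (SE 0.34)), Fos (-1.86 (SE 0.33)) and Mmp8 (-1.59 (SE 0.30)), chosen after their values were seen, passed the test of the difference between responses. The ribosome biogenesis response of V449E cells lay above that of FI-Delta cells for 13 of 31 genes (median log2 0.43, adjusted p = 1.30e-14, and adjusted p = 0.124 with an estimated correlation). The late granule response lay below it for 5 of 22 (median log2 -0.67, adjusted p = 1.13e-09, and adjusted p = 0.117 with an estimated correlation).

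FI-Delta cells without factor and parental cells in GM-CSF differed at few probes at 72 hours, and the cell cycle lists were lower in FI-Delta cells at the preset correlation but not with an estimated one. Klk1b24, a kallikrein, was 2.15-fold higher in FI-Delta cells (adjusted p = 1.02e-07) and Fos higher by 1.12 (SE 0.23, adjusted p = 0.0194). Slc25a26, a mitochondrial carrier, was higher by 1.15 (SE 0.16) and 3110009F21Rik by 1.20 (SE 0.19). Neat1, a nuclear long noncoding RNA, was higher by 1.29 (SE 0.27) and Tcp11l2 by 1.08 (SE 0.22). Klk1b2-ps at 1.40 (SE 0.16) and Neb at 1.40 (SE 0.27) passed on 1 of 2 and 1 of 4 probes. S100a10 was lower at -1.38 (SE 0.17, adjusted p = 7.27e-05) and Cpa3 at -1.27 (SE 0.24, adjusted p = 0.00929). The fatty acid desaturases Scd1 and Scd2 were lower at -1.12 (SE 0.16) and -0.72 (SE 0.17), and Slc43a3 at -0.996 (SE 0.22). Also lower were Syce2 at -0.98 (SE 0.17), Mcm6 at -0.89 (SE 0.15) and Phgdh at -0.77 (SE 0.11). FI-Delta cells already lay below parental cells at 0 hours for S100a10 (-1.02), Slc43a3 (-0.94), Syce2 (-0.64), Scd1 (-0.48) and Mcm6 (-0.36). Scd2 (-0.20), Cpa3 (-0.10) and Phgdh (-0.02) differed less. In G1/S and DNA replication 6 of 34 were lower (19 adjusted over the list alone). The list had a median log2 of -0.32 (adjusted p = 5.91e-16, and adjusted p = 0.0942 with an estimated correlation). In G2/M and mitosis 5 of 37 were lower (22 adjusted over the list alone). Bub1, a spindle checkpoint kinase, was at -0.72 (SE 0.16) and Kif20a, a mitotic kinesin, at -0.58 (SE 0.14). The list had a median log2 of -0.35 (adjusted p = 4.97e-16, and adjusted p = 0.124 with an estimated correlation). The responses from 0 hours differed less, by a median of -0.17 (G1/S) and -0.22 (G2/M). ERK targets were higher for 2 of 28 (6 adjusted over the list alone), Fos and Egr2, an immediate early gene, at 0.76 (SE 0.11). The list had a median log2 of 0.18 (adjusted p = 1.42e-06, and adjusted p = 0.116 with an estimated correlation). Macrophage genes were higher for 1 of 45 (6 adjusted over the list alone). The list had a median log2 of 0.16 (adjusted p = 5.69e-06, and adjusted p = 0.116 with an estimated correlation). The late granule list was higher, with a median log2 of 0.33 (adjusted p = 2.22e-06, and adjusted p = 0.106 with an estimated correlation) and 3 genes higher adjusted over the list alone. NADPH oxidase was higher, with a median of 0.18 (adjusted p = 0.0378, and adjusted p = 0.293 with an estimated correlation) and 1 gene higher adjusted over the list alone. Cholesterol synthesis was lower, with a median of -0.23 (adjusted p = 1.13e-06, and adjusted p = 0.212 with an estimated correlation) and 5 genes lower adjusted over the list alone. Ribosome biogenesis was lower, with a median of -0.16 (adjusted p = 1.65e-05, and adjusted p = 0.267 with an estimated correlation). No member of these 4 lists passed over all genes in limma, and at an unadjusted p under 0.05 there were 10 higher and 0 lower late granule, 1 higher and 0 lower NADPH oxidase, 0 higher and 8 lower cholesterol synthesis and 0 higher and 7 lower ribosome biogenesis genes. The p53 list was higher, with a median of 0.09 (adjusted p = 0.0286, and adjusted p = 0.375 with an estimated correlation), and held 1 higher gene, Btg2, at 0.58 (SE 0.12), also 1 adjusted over the list alone. Csf2ra was 0.15 (SE 0.15), Csf2rb2 -0.07 (SE 0.22) and Il3ra -0.05 (SE 0.06), and none of these passed. In all, 112 probes were higher and 81 lower in FI-Delta cells, 18 and 3 of them at least 2-fold. Replicates correlated at r = 0.44 across probes.

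Single RNAs mattered in the comparison of FI-Delta with GM-CSF cells. Without FI-Delta 72 hours replicate 1 the 193 probes became 44, and 9 of the 16 genes named by size no longer passed. These were Fos (0.77), Cpa3 (-1.32), Neat1 (1.15), Neb (1.44), Mcm6 (-0.70), Scd2 (-0.60), Slc43a3 (-0.83), Syce2 (-0.89) and Tcp11l2 (0.95). Without GM-CSF 72 hours replicate 1, Cpa3 (-1.01), Neb (1.18), Slc43a3 (-0.67) and Tcp11l2 (0.90) no longer passed. Without GM-CSF 72 hours replicate 2, the same held for Fos (1.00), 3110009F21Rik (0.97), Neat1 (0.75) and Scd2 (-0.45). Without FI-Delta 72 hours replicate 2 it held for Cpa3 (-0.88). The p53 list was lost without GM-CSF 72 hours replicate 1 (adjusted p = 0.208) or 2 (adjusted p = 0.0613) or FI-Delta 72 hours replicate 1 (adjusted p = 0.632). The NADPH oxidase list was lost without GM-CSF 72 hours replicate 1 (adjusted p = 0.197) or FI-Delta 72 hours replicate 2 (adjusted p = 0.0879). All replicate 2 arrays of this comparison lie in print run 2. Leaving it out keeps only GM-CSF replicate 1 and says little about stability.

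The 72-hour responses of FI-Delta cells and of GM-CSF cells overlapped. In both, 453 probes rose and 507 fell, with none called in opposite directions, where 43.0 and 47.2 would be shared by independent lists. Because arrays link the fitted levels, unchanged data can share more than independent lists, and the overlap was not simulated. Among the shared genes were Psap, Tmtc2, Rab27b, F2r and Cpa3. In V449E cells at 72 hours these stood at 1.38, 0.19, 0.12, -0.26 and -0.09, and none passed. Across 21797 probes, which are not independent replicates, the FI-Delta and GM-CSF responses correlated at r = 0.78 (Spearman 0.72). Simulated unchanged data on the same arrays gave 0.22. The covariance was 0.0375 beside 0.00197. Within replicates 1 and 2 the correlation was 0.70 and 0.58. The V449E response at 72 hours correlated with that of GM-CSF cells at 0.26 (Spearman 0.21, simulated 0.12, covariance 0.00531 beside 0.00112) and with that of FI-Delta cells at 0.19 (Spearman 0.11, simulated 0.23, covariance 0.00497 beside 0.00205).

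At 12 hours 21 of 31 ribosome biogenesis genes fell in FI-Delta cells (27 adjusted over the list alone), with a list median log2 of -0.43 (adjusted p = 6.01e-25, and adjusted p = 0.0236 with an estimated correlation). In V449E cells 5 fell (19 adjusted over the list alone), with a median of -0.26 (adjusted p = 6.58e-16, and adjusted p = 0.0762 with an estimated correlation). In GM-CSF cells 6 fell (18 adjusted over the list alone), with a median of -0.25 (adjusted p = 6.46e-13, and adjusted p = 0.110 with an estimated correlation). STAT5 targets fell at 12 hours for 7 genes in FI-Delta cells (9 adjusted over the list alone), with a median of -0.27 (adjusted p = 2.12e-05, and adjusted p = 0.141 with an estimated correlation). In GM-CSF cells 2 fell (4 adjusted over the list alone), and the list had a median log2 of -0.17 (adjusted p = 2.12e-05, and adjusted p = 0.141 with an estimated correlation). At 24 hours in GM-CSF 10 of 19 cholesterol synthesis genes fell (17 adjusted over the list alone). The cholesterol synthesis list had a median log2 of -0.56 (adjusted p = 2.09e-23, and adjusted p = 0.0301 with an estimated correlation). Macrophage genes rose in GM-CSF for 12 at 24 hours (19 adjusted over the list alone), with a median of 0.29 (adjusted p = 8.76e-17, and adjusted p = 0.0231 with an estimated correlation). In FI-Delta cells 12 rose at 48 hours (22 adjusted over the list alone), and the list had a median log2 of 0.36 (adjusted p = 1.34e-12, and adjusted p = 0.0447 with an estimated correlation). In GM-CSF 63 probes were higher and 33 lower at 6 hours, 266 and 371 at 12 hours, 178 and 62 at 24 hours and 163 and 125 at 48 hours. FI-Delta cells had 65 and 93 at 6 hours, 388 and 714 at 12 hours, 199 and 111 at 24 hours and 530 and 438 at 48 hours. At 12 hours V449E and FI-Delta cells shared 84 higher and 123 lower probes, where 2.08 and 5.27 would be shared by independent lists, and V449E and GM-CSF cells 51 and 95 (1.43 and 2.74). Here too the link through arrays can raise the overlap of unchanged data above these values. FI-Delta against GM-CSF cells differed at 91 higher and 16 lower probes at 6 hours, 50 and 17 at 12 hours, 29 and 9 at 24 hours and 46 and 17 at 48 hours. At 6 hours 3 late granule genes were higher in FI-Delta cells (9 adjusted over the list alone). As a list they had a median log2 of 0.58 (adjusted p = 3.04e-15, and adjusted p = 0.0231 with an estimated correlation).

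**Figure D2:**
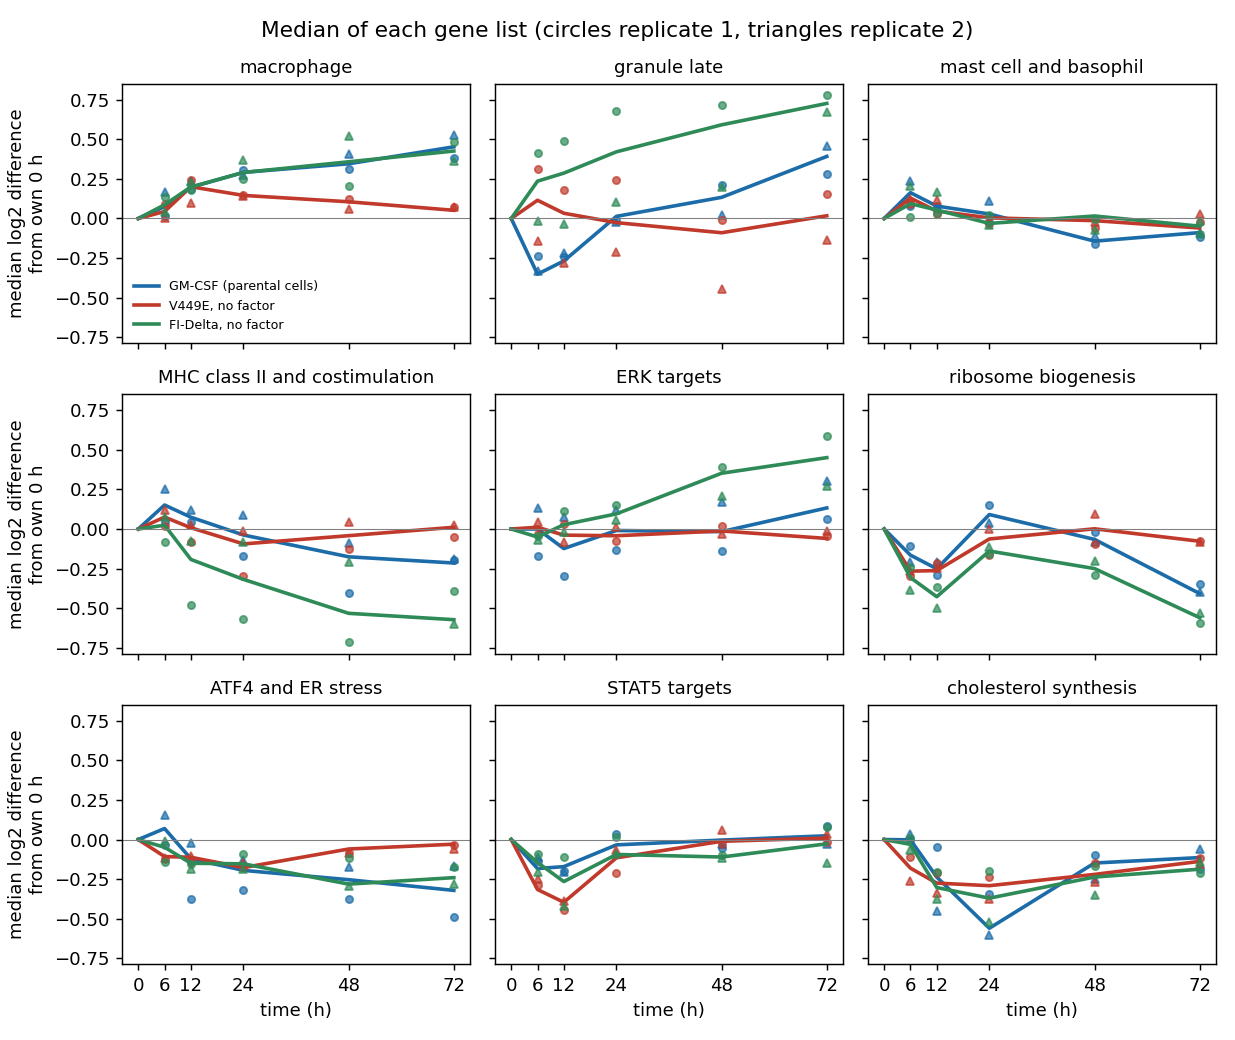
Median log2 difference from the same line at 0 hours (vertical axis) of 9 gene lists against hours after IL-3 was washed out, with lines for the mean of 2 replicates and symbols for each replicate, in parental cells in GM-CSF, V449E cells and FI-Delta cells. At 72 hours the late granule median is 0.73 in FI-Delta, 0.39 in GM-CSF and 0.02 in V449E cells, ribosome biogenesis is -0.56, -0.41 and -0.08, and STAT5 targets reach -0.40 in V449E cells at 12 hours.

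In IL-3, before factor was removed, V449E cells had lower RNA of the late granule list than parental cells at the preset correlation but not with an estimated one. Stfa1 was lower at -2.77 (SE 0.41, adjusted p = 7.67e-04), S100a9 at -2.56 (SE 0.48, adjusted p = 0.00959) and Ngp at -2.54 (SE 0.52, adjusted p = 0.0191). Also lower were S100a8 at -2.41 (SE 0.43), Stfa3 at -2.31 (SE 0.40), Camp at -2.03 (SE 0.46) and Egln3, a prolyl hydroxylase that acts on HIF, at -2.02 (SE 0.30). Itgb2l, an integrin chain of neutrophils, was at -2.08 (SE 0.32) on 1 of 2 probes. Higher were Tmem141 at 1.54 (SE 0.17, adjusted p = 2.11e-05) and Igf2r, a receptor for lysosomal enzymes, at 1.26 (SE 0.13, adjusted p = 9.69e-06). Clec4n was higher at 1.29 (SE 0.26), S100a10 at 1.22 (SE 0.17) and 3110009F21Rik at 1.41 (SE 0.19), as were Ctnna2 at 1.16 (SE 0.23), Cenpl, a centromere protein, at 1.15 (SE 0.23) and, on 1 of 2 probes, Ms4a6d at 1.18 (SE 0.21). Late granule genes were lower for 5 of 22 (10 lower and 1 higher adjusted over the list alone). The list had a median log2 of -0.39 (adjusted p = 1.71e-07, and adjusted p = 0.0942 with an estimated correlation). Macrophage genes were higher for 4 of 45 (8 adjusted over the list alone). Mmp12, the macrophage elastase, was at 1.01 (SE 0.20) and Cd68, a lysosomal glycoprotein, at 0.89 (SE 0.15). The list had a median log2 of 0.27 (adjusted p = 1.06e-11, and adjusted p = 0.0547 with an estimated correlation). MHC class II genes were higher for 2 of 13 (8 adjusted over the list alone), with H2-DMa, a peptide-loading chain, at 0.60 (SE 0.10). The list had a median log2 of 0.52 (adjusted p = 1.16e-09, and adjusted p = 0.0706 with an estimated correlation). Of 34 G1/S genes 3 were lower (17 adjusted over the list alone), with Cdc45, a replication factor, at -0.64 (SE 0.13). The G1/S list had a median log2 of -0.25 (adjusted p = 1.15e-18, and adjusted p = 0.0838 with an estimated correlation). Of 37 G2/M genes 1 was lower (15 adjusted over the list alone), Cdca8, a chromosomal passenger protein, at -0.49 (SE 0.09). The G2/M list had a median log2 of -0.29 (adjusted p = 4.65e-16, and adjusted p = 0.124 with an estimated correlation). Cholesterol synthesis was lower for 1 of 19 (6 adjusted over the list alone). The list had a median log2 of -0.22 (adjusted p = 3.16e-09, and adjusted p = 0.121 with an estimated correlation). STAT5 targets were higher as a group, with a median of 0.19 (adjusted p = 8.74e-04, and adjusted p = 0.186 with an estimated correlation) and 2 genes higher adjusted over the list alone. The interferon list was higher, with a median of 0.08 (adjusted p = 0.00472, and adjusted p = 0.0942 with an estimated correlation). Progenitor regulators were higher, with a median of 0.04 (adjusted p = 0.0177, and adjusted p = 0.124 with an estimated correlation) and 3 genes higher adjusted over the list alone. NADPH oxidase was lower, with a median of -0.17 (adjusted p = 0.0170, and adjusted p = 0.214 with an estimated correlation) and 1 gene lower adjusted over the list alone. No member of these 4 lists passed over all genes in limma, and at an unadjusted p under 0.05 there were 6 higher and 2 lower STAT5 target, 3 higher and 0 lower interferon, 5 higher and 0 lower progenitor and 0 higher and 1 lower NADPH oxidase genes. Csf2ra was 0.10 (SE 0.15), Csf2rb2 0.42 (SE 0.22) and Il3ra 0.13 (SE 0.06), and none of these passed. In all, 101 probes were higher and 59 lower in V449E cells, 15 and 13 of them at least 2-fold. Replicates correlated at r = 0.51 across probes.

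This comparison was made in both print runs, whose means correlated at r = 0.51 across probes. Limma called 301 probes within print run 1 and 24 within print run 2. The late granule median was -0.58 in run 1 and -0.15 in run 2, and the macrophage median 0.29 and 0.22. S100a9 was -2.49 and -2.42, Stfa1 -2.80 and -2.96, Stfa3 -2.88 and -0.90 and Cenpl 1.75 and 0.29 in runs 1 and 2. Without print run 2 arrays 337 probes passed. The count of 160 became 4 without V449E 0 hours replicate 1 and 38 without replicate 2. It became 68 without parental 0 hours replicate 1 and 35 without parental 0 hours replicate 2. Of the 16 genes named by size, 15 no longer passed without V449E 0 hours replicate 1. These were all but Igf2r (1.40), for example S100a9 (-1.28) and Stfa1 (-2.13). Without V449E replicate 2, 4 of the 16 were lost (Clec4n at 1.54, Ctnna2 at 1.15, Cenpl at 1.11 and Stfa3 at -2.79). Without parental replicate 1, 8 were lost (Ngp at -2.84 and Egln3 at -1.82 among them). Without parental replicate 2, 9 were lost (S100a8 at -2.02, S100a9 at -2.24 and Camp at -1.56 among them). All 16 kept their sign throughout. Their median ratio to the difference with all RNAs was 0.86 without V449E replicate 1 and 1.20 without V449E replicate 2. It was 1.13 without parental replicate 1 and 0.92 without parental replicate 2. A lone RNA raises the error, so part of these losses needs no smaller difference. Further lists passed only when 1 RNA was left out, most often without parental 0 hours replicate 1. Of the lists, progenitor regulators (adjusted p = 0.0529 without V449E replicate 1 and adjusted p = 0.112 without parental replicate 2), NADPH oxidase (adjusted p = 0.103 and adjusted p = 0.101) and interferon response (adjusted p = 0.0942 without V449E replicate 1) were lost. FI-Delta cells differed from parental cells at 0 hours by 20 higher and 3 lower probes. The direct arrays here lie in print run 1 for replicate 1 and print run 2 for replicate 2. Here the replicates correlated at r = 0.03 across probes, and 696 probes had an unadjusted p under 0.05 where 1090 would be drawn by chance. Of 45 macrophage genes 2 were higher (9 adjusted over the list alone), and the list median was 0.28 (adjusted p = 1.89e-20, and adjusted p = 0.0206 with an estimated correlation). Among the called probes Clec4n at 1.67 (SE 0.26), Mmp8 at 1.31 (SE 0.21) and Igfbp4, a binding protein of insulin-like growth factors, at -1.05 (SE 0.17) were chosen after their values were seen.

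**Figure D3:**
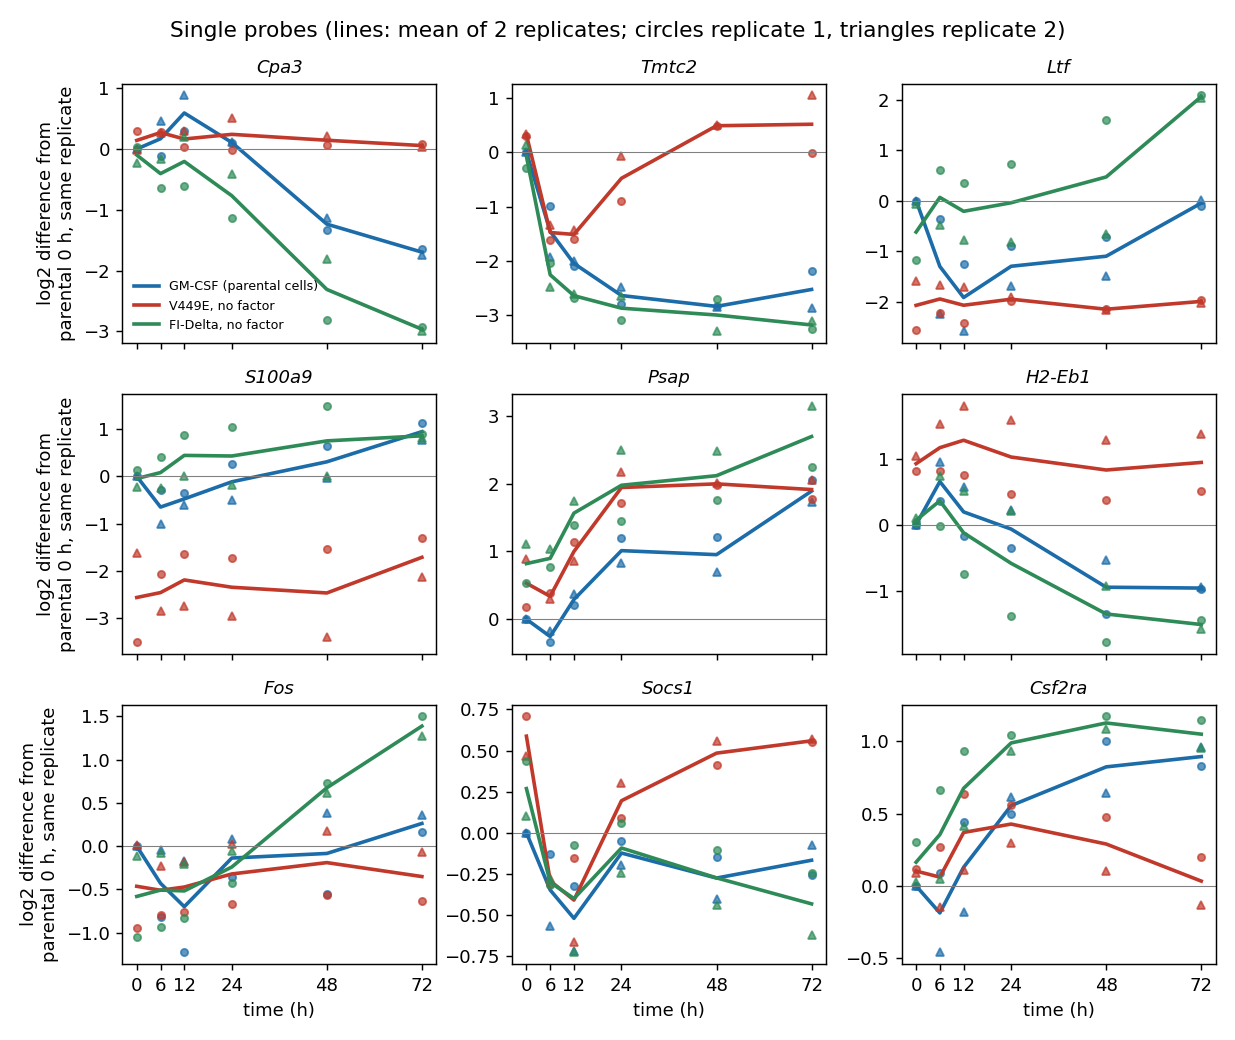
Log2 difference from parental cells at 0 hours of the same replicate (vertical axis) of 9 probes against hours after IL-3 was washed out, with lines for the mean of 2 replicates, circles for replicate 1 and triangles for replicate 2, in parental cells in GM-CSF, V449E cells and FI-Delta cells. Against its own 0 hours, Cpa3 is at -1.70 in GM-CSF and -2.87 in FI-Delta cells at 72 hours, and Tmtc2 is at -1.83 in V449E cells at 12 hours and at 0.19 by 72 hours.

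Several list results at 72 hours did not pass as groups while single members did. Primary granule genes had 1 of 14 lower in GM-CSF at 72 hours, Cebpa, a transcription factor of granulocyte commitment, at -0.67 (SE 0.17) (median log2 -0.03, adjusted p = 0.558), also 1 adjusted over the list alone. In FI-Delta cells 2 were higher and 1 lower (median log2 0.18, adjusted p = 0.634), or 3 and 3 adjusted over the list alone. Erythroid and megakaryocyte genes had 1 of 17 higher and 2 lower in GM-CSF (2 and 2 adjusted over the list alone). Itga2b, a platelet integrin, was lower at -0.89 (SE 0.15) and in FI-Delta cells at -1.15 (SE 0.15) (list median log2 -0.06, adjusted p = 0.514 in GM-CSF). In FI-Delta cells Cd3d, a T cell receptor chain of the lymphoid list, was higher at 0.76 (SE 0.15). There 2 of the 19 lymphoid genes rose and 1 fell, also 2 and 1 adjusted over the list alone, and the list did not move as a group (median log2 -0.0030, adjusted p = 0.817). The glycolysis list had a median of -0.01 in GM-CSF (adjusted p = 0.879) and -0.12 in FI-Delta against GM-CSF cells (adjusted p = 0.0946), where it passed without GM-CSF 72 hours replicate 1 (-0.23, adjusted p = 0.00108). Interferon response genes in V449E against FI-Delta cells at 72 hours went both ways, 4 higher and 4 lower of 28, also 4 and 4 adjusted over the list alone. Ifit1, an RNA-binding effector, was at 0.84 (SE 0.15) and Oasl2 at -0.64 (SE 0.14) (median log2 0.03, adjusted p = 0.799). In GM-CSF at 72 hours progenitor regulators had 2 genes higher and 2 lower of 26 (3 and 2 adjusted over the list alone). Id2 was at 1.66 (SE 0.21) and Myb, a progenitor transcription factor, at -0.88 (SE 0.14). The median (-0.05) and the mean (0.02) differed in sign (adjusted p = 0.753). The median, mean and test differed in sign for 17 of the 132 list tests, none of which passed, the smallest adjusted p among them being 0.481.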

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

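Of the tests in this part, that of compressed ratios in print run 2 was written before its result was seen, and the others were chosen after.

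V449E cells changed at 6 to 24 hours and had no called probe at 72 hours, and the test of the difference between responses separated them from FI-Delta cells at 783 probes and from GM-CSF cells at 137. Tmtc2, Cpa3 and Fos were among the 783. Noisier V449E RNAs at 72 hours would leave most of the 24-hour response in place, but the part of it kept at 72 hours, measured only across different replicates, was 0.332 (0.271 and 0.393 in the crossings of replicates), which argues against that explanation. A change shared by the lines after the wash, mostly lost again in V449E cells, remains open as a hypothesis. Psap was not lost, at 1.41, 1.46 and 1.38 at 24, 48 and 72 hours, though not passing at 48 and 72 hours. With noise removed, the 12-hour V449E response correlated across replicates at 0.923 with GM-CSF cells and 0.960 with FI-Delta cells. A common early change would give such estimates, which can exceed 1, as between FI-Delta and GM-CSF cells at 12 hours (1.13). The observed V449E replicates correlated at r = 0.50 at 12 hours. A difference between the receptor mutants, which the design names, was not tested apart from the line.

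The 72-hour response called more probes in FI-Delta than in GM-CSF cells (3326 and 1192), although the direct test of the difference between responses found 1, Klk1b24 at 0.98 (SE 0.12), with 792 at an unadjusted p under 0.05 and 1481 by limma on single arrays. Compressed ratios in print run 2 as the whole cause would bring the amplitude ratio of the lines near 1 in replicate 1, whose GM-CSF arrays all lie in print run 1. It was 1.34 there and 1.56 in replicate 2. The standard errors of 0.0240 and 0.0301 come from resampling probes and hold no spread between RNAs, and the replicates, with 1 RNA per condition each, differed by a standard deviation of 0.157. Compressed ratios and a larger response thus cannot be told apart, because a single replicate of the GM-CSF series lies outside print run 2. That both lines ran 1 programme at different amplitudes may hold, since the correlation across replicates with noise removed was 1.02, a value that can exceed 1. Whether this reflects the mutant, the factor, the print run or the pace of the change stays open.

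At 0 hours the late granule list was lower in V449E than in parental cells at the preset correlation, with 5 of 22 members called, and missed the threshold with an estimated one (adjusted p = 0.0942). Without V449E 0 hours replicate 1, S100a9 shrank to -1.28 and Ngp to -1.33. Print run as the cause would leave the list at or above 0 in a run. Its median was -0.58 in run 1 and -0.15 in run 2, with 17 of 22 members below 0 in each. The 95% upper bounds were -0.12 and -0.0027, but 0.40 and 0.16 with the correlation of members counted. This list thus cannot tell print run from a line difference. All 160 called probes, chosen on these arrays, kept their sign in both runs. Parental RNAs high in granule genes would lower FI-Delta cells as much, but against the same parental RNAs their median was -0.036 (-0.10 and -0.01 in the replicates, beside -0.51 and -0.30 for V449E). These FI-Delta medians argue against parental RNA as the whole cause. V449E cells lay below FI-Delta cells at -0.36 (camera, adjusted p = 0.0262 with an estimated correlation). That value comes from the same fit, parental arrays included, and is not separate evidence. A property of the V449E line may remain as a hypothesis, found and tested on the same data. Whether the receptor mutant or the making of the line gives it was not tested.

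Gene lists that differed in response at the preset correlation numbered 11 of 22 between V449E and FI-Delta cells, 8 between FI-Delta and GM-CSF cells and 12 between V449E and GM-CSF cells, and with an estimated correlation camera called 0 in each. The array of GM-CSF at 72 hours against parental cells, replicate 1, in one orientation, had a median absolute deviation of 0.0981, far from the other 3 arrays of its group. It was the single such array among 28 groups tested, where chance gives about 1 in 20. Of 375 empty and buffer spots, 8 passed in V449E against FI-Delta cells at 72 hours, with a median log2 of 0.07, and 4 of the 28 comparisons had any that passed. Another 231 mouse control spots had medians of -0.11, -0.09 and -0.09 at 12 hours in GM-CSF, V449E and FI-Delta cells. Of them 34.2%, 25.5% and 26.4% had an unadjusted p under 0.05 in limma. The remaining 637 controls had medians of -0.03, -0.0041 and -0.02 there. Whether this bears on the change shared at 12 hours was not tested.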

How the results depend on the processing

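One alternative, the correlation between print runs over the called probes only, was chosen after seeing the data. The self-test found changes of 1 on the log2 scale nearly always with 2 replicates, in probes drawn at random. This need not hold for other probes. In V449E cells at 72 hours Psap at 1.38 and S100a9 at 0.85 did not pass. Leaving out an RNA assumes that its lone partner varies like the other conditions. In the order GM-CSF, V449E and FI-Delta at 72 hours against 0 hours, V449E against parental cells at 0 hours, V449E against FI-Delta and FI-Delta against GM-CSF cells at 72 hours, limma on single arrays called 3668, 266, 7230, 4754, 6645 and 2216 probes, with a dye effect 3960, 370, 7654, 5135, 7074 and 2504, and on dye-swap means 2878, 31, 6533, 4033, 6044 and 1362. These treat repeated measurements of the same RNAs as replicates, which gives smaller errors by construction. On single arrays the other times called 50958 probes beside 7850, and the differences between responses 6542 (V449E and FI-Delta), 1481 (FI-Delta and GM-CSF) and 1982 (V449E and GM-CSF). Direct arrays only called 29 in V449E cells at 72 hours and 290 in FI-Delta against GM-CSF cells, and gave 0.67 for the correlation of the GM-CSF and FI-Delta responses. Without the replicate block 292 passed in FI-Delta against GM-CSF cells, and in the others 1403, 0 (V449E at 72 hours, limma, 933 at an unadjusted p under 0.05), 3601, 196 and 3962. The block had nothing to remove from centred levels, so leaving it out only counted 1 more residual degree of freedom. No array joins the replicates, and deviations of the replicates correlated between conditions at a median of -0.07 where the centring gives -0.06 by itself, so whether the numbers pair the samples stayed open. Scaled arrays called 750, 1576, 103, 1943 and 90 probes in the 5 comparisons that had calls. Without print run 2 arrays 337 passed in V449E against parental cells and 125 in FI-Delta against GM-CSF cells. With an estimated correlation 2 list tests passed. Over the called probes, which were selected on the same arrays, the print runs correlated at 0.885 in place of 0.508. Turning all signs would give the late granule list -0.39 in GM-CSF at 72 hours. Apart from the construction of the array and dye-swap fits, the cause was not tested.

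Leaving out 1 RNA gave 411 to 749 probes for GM-CSF at 72 hours, 0 to 47 for V449E (limma, 933 at an unadjusted p under 0.05 with all RNAs), 1053 to 2346 for FI-Delta, 4 to 68 for V449E against parental cells, 2076 to 2641 for V449E against FI-Delta and 44 to 222 for FI-Delta against GM-CSF cells. The ERK target list in GM-CSF ranged from -0.037 to 0.33 and turned sign without parental 0 hours replicate 2. Median centring and robust moderation left each of these 6 counts within 1.5 times. With no value missing, complete probes and 1 orientation per pair repeat the main fit and say nothing about stability. Without these 2, of 1120 values for 80 gene results 1028 kept their direction and side of the threshold, 92 no longer passed and 0 turned, and 44 of the 80 results passed in all. Of 1188 values for 132 list results, 1036 kept their side of the threshold, 114 no longer passed, 37 newly passed and 1 turned. Direction was compared only for the 59 that passed at first, so a newly passing value can point the other way. The other times and the differences between responses had only the single-array alternative.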

Other observations

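The gene groups in this part, and their tests, were chosen after values had been seen, and every test named here is of that kind. At 6 hours genes of the oxidative stress regulator NRF2 and of iron storage were higher in all 3 cell populations, with 5 of 19 measured genes rising in GM-CSF (median log2 0.28, adjusted p = 2.60e-12, and adjusted p = 0.0654 with an estimated correlation), 3 in V449E cells (median log2 0.22, adjusted p = 1.30e-09, and adjusted p = 0.0714 with an estimated correlation) and 5 in FI-Delta cells (median log2 0.37, adjusted p = 4.91e-12, and adjusted p = 0.0654 with an estimated correlation). At 72 hours the group passed in none of the 3 populations (adjusted p = 0.321 in GM-CSF, adjusted p = 0.558 in V449E and adjusted p = 0.314 in FI-Delta cells), while single members did. In GM-CSF 2 rose, Fth1 by 1.13 and Nqo1 by 0.36, and in FI-Delta cells 4 rose and 3 fell, such as Slc40a1, the iron exporter, at 1.12 and Gclc at -0.64. In V449E cells limma called 0, with 2 higher and 2 lower at an unadjusted p under 0.05. Slc7a11, the cystine transporter, rose at 6 hours by 1.64, 1.38 and 1.76 in GM-CSF, V449E and FI-Delta cells, Hmox1, heme oxygenase, by 1.47, 0.96 and 1.13, and Gclc, the catalytic subunit of glutathione synthesis, by 1.17, 0.71 and 0.86. Of 45 lysosome genes, 11 of which also stand in the fixed lists, 9 rose in V449E cells at 24 hours (median log2 0.28, adjusted p = 3.65e-18, and adjusted p = 0.0714 with an estimated correlation), 5 in GM-CSF (median log2 0.24, adjusted p = 3.62e-13, and adjusted p = 0.0776 with an estimated correlation) and 9 in FI-Delta cells (median log2 0.27, adjusted p = 4.27e-14, and adjusted p = 0.0776 with an estimated correlation). At 72 hours 14 rose in GM-CSF (median log2 0.25, adjusted p = 4.91e-12, and adjusted p = 0.0856 with an estimated correlation) and 21 in FI-Delta cells (median log2 0.27, adjusted p = 2.99e-08, and adjusted p = 0.144 with an estimated correlation). In V449E cells limma called 0 lysosome genes at 48 hours (median log2 0.11, adjusted p = 6.03e-07, and adjusted p = 0.176 with an estimated correlation) and 0 at 72 hours (median log2 0.09, adjusted p = 2.98e-08, and adjusted p = 0.144 with an estimated correlation), with 13 higher and 1 lower and 5 higher and 0 lower at an unadjusted p under 0.05. The 15 genes of secretory granule traffic went both ways. In GM-CSF 3 fell at 48 hours (median log2 -0.07, adjusted p = 0.00902, and adjusted p = 0.0776 with an estimated correlation), and 2 rose and 2 fell at 72 hours (median log2 -0.02, adjusted p = 0.279, and adjusted p = 0.340 with an estimated correlation). In FI-Delta cells 4 rose and 3 fell at 48 hours (median log2 -0.03, adjusted p = 0.813, and adjusted p = 0.820 with an estimated correlation), and 4 and 2 at 72 hours (median log2 0.02, adjusted p = 0.458, and adjusted p = 0.512 with an estimated correlation). Limma called 0 of the 15 genes in V449E cells at 48 hours (median log2 -0.10, adjusted p = 0.00351, and adjusted p = 0.0714 with an estimated correlation) and 0 in FI-Delta against GM-CSF cells at 72 hours (median log2 0.06, adjusted p = 0.0137, and adjusted p = 0.0776 with an estimated correlation), with 0 higher and 2 lower and then 4 higher and 0 lower at an unadjusted p under 0.05. These groups were tested together over 84 tests.

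At 12 hours 46 probes were higher and 87 lower in all 3 populations, where independent lists would share 0.0254 and 0.0898. The fitted levels of the populations are linked through arrays, so unchanged data can share more, and no overlap was simulated. Slc15a3, a lysosomal peptide transporter, was higher by 1.40 in GM-CSF, 0.87 in V449E and 1.22 in FI-Delta cells, and Fth1 by 1.39, 1.09 and 0.89. Atf4 was lower at -1.31, -1.32 and -1.12, and Chac1, a glutathione-degrading enzyme and ATF4 target, at -1.04, -1.17 and -0.95. Tmtc2 was lower at -2.04, -1.83 and -2.56 at 12 hours, and at 72 hours it stood at 0.19 in V449E and -3.10 in FI-Delta cells.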
